A study of Hordeum vulgare with 60 samples.

How the data were processed

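Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on leaves of 2 hulless barley lines, G7, labelled resistant, and Z13, labelled susceptible. Plants were sprayed with Blumeria graminis f. sp. hordei, the fungus that causes barley powdery mildew, and leaves were taken at 0, 6, 36, 72 and 168 h. H3K4me3, a histone mark found at the starts of active genes, and H3K27me3, the mark of Polycomb silencing, were each measured in 2 replicates per line and time. This gave 40 ChIP libraries with a peak list each. The 20 input libraries were not analysed here. The labels do not say whether replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical.

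Reads were trimmed with Trimmomatic, aligned with BWA and peaks were called with MACS2 2.1.1, per the submitters' processing notes. The genome build and the peak calling settings are not given in the sources used here. The deposited lists are 1 per ChIP library, so replicates were not pooled. Per the file headers, each peak has a tag count, a p-value, a q-value and a fold enrichment, all set by the authors. The largest deposited q-value was 0.0999. The deposited fold enrichment of a peak was used only to describe or rank peaks within its own list. The deposited lengths are in bp, and the deposited summit lay within 2 bp of the middle of the peak, so the authors' gene features follow the peak middle. Depth is known only as tags inside peaks, and the total reads of a library were not used here.

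A gene was taken to carry a mark in a library when the authors placed a peak in it or in its promoter, which reached about 2000 bp upstream. The annotation in the files holds 33562 genes, of which 33404 have a position and 16185 a KEGG name. Names are KEGG names of similar proteins as deposited, and many come from animals or bacteria. Coordinates are 1-based as in the files.

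Presence of a peak was compared per gene with Fisher's exact test between lines, and with an exact conditional test stratified by line for 0 h against infected leaves and for early (0 and 6 h) against late (36, 72 and 168 h) leaves. All were two-sided with Benjamini-Hochberg adjustment at 0.05, over genes with a peak in some but not all 20 libraries of a mark. Peak number and covered length were compared by exact permutation of log2 values, within time points for lines and within lines for infection. Similarity of peak lists was the Jaccard index over bases, tested one-sided by exact permutation of the assignment of replicates to time points. Association of both marks over genes was the log2 odds ratio of a pair of libraries, tested by sign flips over the pairs (100000 drawn, two-sided). Gene lists were compared by the share of members with a peak over the share of other genes, on the log2 scale with 0.5 added to each count, where the plan for comparisons between groups had named all genes as the denominator. The tests were exact permutation between groups and sign flips against other genes, both two-sided. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

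The tests were checked on simulated data with 200 changed genes. Between lines, 39.5% of H3K4me3 genes present in shares of 0.1 and 0.9 of libraries were recovered, and 100% of genes present in none and all; for H3K27me3 these were 40% and 100%. Early against late, 34.5% and 37% of genes with shares of 0.1 and 0.9 were recovered for H3K4me3 and H3K27me3, and 100% of genes present in none and all. For 0 h against infected leaves, 0% of H3K4me3 genes with shares of 0.1 and 0.9 were recovered, and 100% of genes present in none and all. For H3K27me3 in that comparison, 0% were recovered even with shares of 0 and 1, so it could not call 200 such genes. These rates hold for 200 changed genes, since an adjusted p falls as more genes share the smallest p. Fewer such genes can be missed where 200 were recovered. Between lines, HVUL6H01205.2 had H3K27me3 in 0 of 10 G7 and 10 of 10 Z13 libraries and was not called (adjusted p = 0.101, Fisher's exact test).

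Groups, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took up to 10 called genes per direction with the largest difference in the share of libraries, ties going to the smaller p, then to named genes and list members. Where none was called it took the 3 genes per direction with the smallest p. It also took members of gene lists that passed and of preset loci. Gene lists were matched on KEGG names. After names were read, the thionin pattern of the pathogenesis-related list was narrowed because it matched methionine enzymes, and a list of receptor kinases was added, both after totals per gene had been seen and before any list was compared. Lists of NAC factors, seed storage, pollen and root genes matched fewer than 10 genes and were not tested, so markers of other organs give no check here. Alternatives were other gene assignments, a q-value threshold of -log10 q of at least 5, equal numbers of the strongest peaks (17616 per H3K4me3 and 4490 per H3K27me3 library), other strata, a replicate block and leaving out each library. Those added after the data were examined were assignment by overlap with the gene body, the alternatives for lists against other genes, for peak number after infection and for gained and lost genes, 3 filters of the time comparisons, and the block and left-out libraries for gene lists. Tests of similarity within against between lines, of both marks between lines, of list members among called genes, of neighbouring called genes, of H3K27me3 at called genes and of list length at called genes were also added after the data were examined.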

Results

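The 40 peak lists held 1304855 peaks. H3K4me3 lists held 34497 ± 8117 peaks (SD, n = 20) covering 31.2 ± 11.3 Mb, and H3K27me3 lists 30746 ± 20624 peaks (SD, n = 20) covering 45.0 ± 38.1 Mb. Tags in peaks ran from 1712654 to 8201803 in H3K4me3 libraries and from 1052308 to 23180176 in H3K27me3 libraries. H3K4me3 peaks lay within 2000 bp of a gene start in 53.8% ± 5.34 of cases (SD, n = 20), against 19.6% ± 5.98 for H3K27me3 (SD, n = 20). H3K27me3 peaks were intergenic in 74.4% ± 7.05 of cases (SD, n = 20), and 57.0% ± 10.2 lay in the outer 10% at either end of a chromosome, which hold 42.8% of genes. A gene or promoter peak was found for 20361 ± 3169 genes per H3K4me3 library and 6086 ± 3316 per H3K27me3 library (SD, n = 20 each).

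**Figure D1:**
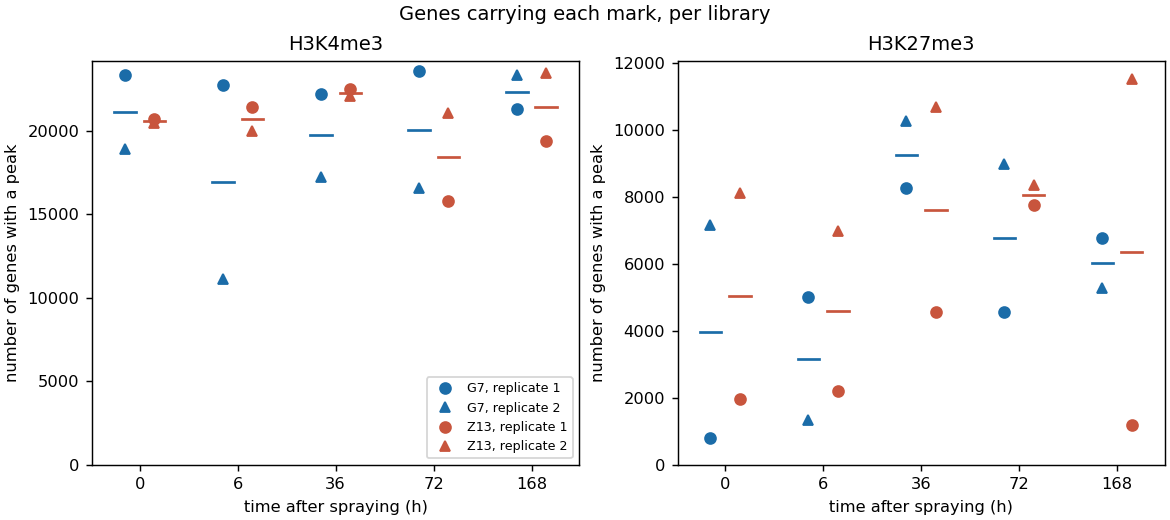
Number of genes with a peak in the gene or promoter against time after spraying (h), for H3K4me3 (left) and H3K27me3 (right). Each point is a library, circles are replicate 1 and triangles replicate 2, blue is G7 and red Z13, and bars are means of 2 replicates. H3K27me3 libraries run from 790 to 11516 genes, and the replicates of Z13 at 168 h lie at 1179 and 11516.

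The kinds of gene carrying each mark were described first. H3K27me3 was found most often, relative to other genes, at pathogenesis-related proteins, secreted antimicrobial proteins such as chitinases, with 43.4% ± 17.5 of members per library (SD, n = 20), 2.73 times the share of other genes and higher in 20 of 20 libraries. Next came phenylpropanoid enzymes of lignin and phenolic synthesis (40.3% ± 17.9), cytochrome P450 enzymes (41.1% ± 22.7), NLR immune receptors, the intracellular sensors of pathogen effectors (36.7% ± 18.0; 311 of the 340 genes listed are named RPM1 and 6 are named for its partner RIN4, which is no receptor), redox enzymes (36.1% ± 17.3) and WRKY defence transcription factors (36.9% ± 19.3). MADS and homeobox factors (37.1% ± 19.1), callose and cell wall genes (34.9% ± 19.5), receptor-like kinases (30.0% ± 18.9), jasmonate and ethylene genes (30.5% ± 17.5) and the added receptor kinases (25.9% ± 14.7) were also above other genes. Ribosomal protein genes carried H3K27me3 least, at 6.16% ± 4.63 of members or 0.294 times the share of other genes. Photosynthesis (7.25% ± 7.37), transposon protein (7.65% ± 7.17; 16 transposases and 1 telomerase), histone (8.15% ± 5.39), SNARE and secretion (9.20% ± 6.47), calcium signalling (11.4% ± 7.06) and chromatin modifier genes (11.7% ± 8.25) were also below other genes. These 18 of 22 lists passed, with a smallest adjusted permutation p of 1.57e-05. Its unadjusted permutation p of 1e-05 is the smallest these permutations can give. This test asks whether a ratio repeats over libraries that score the same genes. Random lists of the same size were not compared, so it does not show that the kind of gene matters. Every list member has a KEGG name, but only 16185 of the 33562 genes do. The ratios therefore also set named genes against other genes that are partly unnamed. Auxin and gibberellin (23.0% ± 14.7), heat shock (22.5% ± 14.4), MLO (19.7% ± 14.7) and F-box and ubiquitin ligase genes (18.0% ± 8.64) did not pass. With the stricter q-value threshold 11 lists passed, the 6 low lists other than ribosomal proteins lay above other genes and the added receptor kinases below them. Callose and cell wall, MADS and homeobox and ribosomal protein genes (adjusted permutation p = 0.199, 0.0794 and 0.0508) and each list that turned other than transposon proteins then did not pass, while MLO and heat shock genes did. Receptor-like kinases did not pass with intergenic peaks assigned (adjusted permutation p = 0.579), nor photosynthesis, histone and chromatin modifier genes with equal numbers (0.0737, 0.0812 and 0.256). With equal numbers of strongest peaks the jasmonate and ethylene and the added receptor kinase genes lay below other genes and the transposon protein genes above, and MLO genes turned below other genes with intergenic peaks assigned. The high share at NLR genes passed under each of these settings. Auxin and gibberellin genes passed with intergenic peaks, within 2000 bp of the start, by overlap and without the G7 6 h library of replicate 2 (adjusted permutation p = 0.0124, 0.00285, 0.00102 and 0.000124). Heat shock genes passed within 2000 bp and without the Z13 168 h library of replicate 1 (0.00139 and 0.0103, permutation), and F-box and ubiquitin ligase genes within 2000 bp, with equal numbers and by overlap (0.000733, 0.000275 and 0.00741, permutation).

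H3K4me3 was found at 83.4% ± 15.3 of WRKY genes (SD, n = 20), 1.36 times the share of other genes. It was also above other genes at the MLO family (81.2% ± 12.5), membrane proteins of which some are known for powdery mildew susceptibility. The same held for phenylpropanoid enzymes (79.0% ± 11.3), F-box and ubiquitin ligases (77.5% ± 10.5), receptor-like kinases (77.3% ± 16) and chromatin modifiers (75.9% ± 8.04). Heat shock proteins (75.3% ± 14.2), calcium signalling (75.0% ± 7.98), auxin and gibberellin (74.1% ± 11) and SNARE genes (72.9% ± 9.26) lay above other genes too. NLR genes carried it less often (53.4% ± 14.3, 0.854 times other genes), as did cytochrome P450 (56.7% ± 14.8) and transposon protein genes (24.7% ± 9.47, 0.410 times other genes). In all, 18 of 22 lists passed, with a smallest adjusted permutation p of 1.83e-05. As for H3K27me3, this shows that ratios repeat over libraries, not that they exceed those of random lists of the same size or of other named genes. For 5 of these the direction turned with equal numbers of strongest peaks and with the stricter threshold: pathogenesis-related (70.5% ± 16.8), redox (70.1% ± 15.3), callose and cell wall (68.7% ± 15.7), the added receptor kinases (63.3% ± 12.3) and ribosomal proteins (56.3% ± 5.0). Histones (64.9% ± 15.0), MADS and homeobox (63.1% ± 13.9), photosynthesis (61.8% ± 6.81) and jasmonate and ethylene genes (60.6% ± 13.4) did not pass, and the histone, MADS and jasmonate lists turned under other settings. All 4 lists passed under some settings. Photosynthesis genes lay above other genes within 2000 bp (log2 ratio 0.33), by overlap (0.24) and with equal numbers (0.10). Histone genes lay above within 2000 bp (0.30), by overlap (0.30) and with intergenic peaks (0.07), but below with equal numbers (-0.24). MADS and homeobox genes lay above within 2000 bp (0.09) and by overlap (0.10), but below with intergenic peaks (-0.04), the stricter threshold (-0.36) and equal numbers (-0.51). Jasmonate and ethylene genes lay below with the stricter threshold (-0.42) and equal numbers (-0.47). In these cases the largest adjusted permutation p was 0.0256. Without the G7 6 h library of replicate 2 the histone and the MADS and homeobox lists passed (adjusted permutation p = 0.0125 and 0.0344). Phenylpropanoid genes did not pass with the stricter threshold (adjusted permutation p = 0.291), receptor-like kinases with equal numbers of peaks (0.855) or cytochrome P450 genes by overlap with the gene body (0.0903). Pathogenesis-related and ribosomal protein genes did not pass with intergenic peaks assigned (adjusted permutation p = 0.291 and 0.391), nor ribosomal protein genes by overlap (0.0554).

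**Figure D2:**
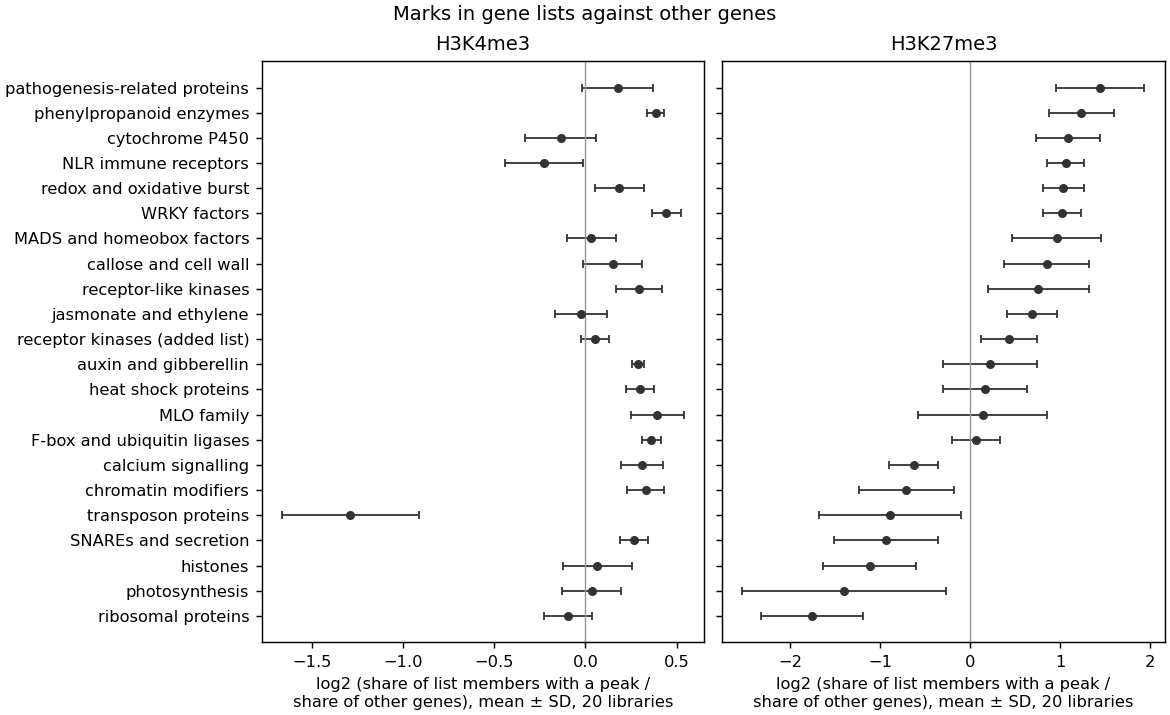
Log2 ratio of the share of list members with a peak to the share of other genes, for H3K4me3 (left) and H3K27me3 (right), 1 row per gene list. Points are means and bars SDs over 20 libraries. Pathogenesis-related genes have the highest H3K27me3 ratio and ribosomal protein genes the lowest.

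Both marks were often called at the same gene. A median of 4039 genes per pair of libraries carried both, and 67.5% ± 15.1 of genes with H3K27me3 had H3K4me3, against 60.7% ± 9.44 of all genes (SD, n = 20 pairs). The log2 odds ratio was 0.59 ± 0.52 (SD, n = 20), above 0 in 16 of 20 pairs (permutation p = 0.00036). As for the lists, this test asks whether the association repeats over pairs that score the same genes. The odds ratio was not adjusted for gene length. The pairs below 0 had H3K4me3 at 11138 to 18888 genes, the others at 17237 to 23564, so list length may matter. Equal numbers of peaks were not tried for this odds ratio. In G7 it was 0.52 ± 0.62 and in Z13 0.65 ± 0.42 (n = 10 each), a difference within the spread (exact permutation p = 0.597). Leaves hold many cell types, and the lists do not tell whether both marks were on the same chromosomes.

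The first comparison asked which genes differed between the resistant and the susceptible line. For H3K4me3, 305 of 18393 genes tested passed, 95 with a peak more often in G7 and 210 more often in Z13. Of these, 121 had a peak in 10 of 10 libraries of one line and 0 of 10 of the other, 24 in G7 and 97 in Z13. No called gene had a peak in more than 2 of 10 libraries of the line lacking the mark. A KEGG name was deposited for 116 of them. Chromosome 2H, with the most tested genes (3270), held 17 of G7 and 42 of Z13.

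Genes with H3K4me3 in 10 of 10 Z13 and 0 of 10 G7 libraries included 3 NLR genes named RPM1, for a receptor that guards against bacterial effectors. They were HVUL2H06661.2 (chromosome 2H, 6868680 to 6871979), HVUL7H19737.2 (7H, 4278159 to 4282899) and HVUL5H14858.2 (5H, 468556454 to 468559828). The same held for HVUL2H31716.2, named for the receptor kinase EFR (2H, 15798736 to 15801821), and HVUL5H45972.2, named for the kinase PBS1 (5H, 438008743 to 438012415). It held for HVUL6H10324.2, a U-box ubiquitin ligase named STUB1 (6H, 457476793 to 457478055), HVUL1H52022.2, a jumonji domain protein (1H, 100303231 to 100303546), and HVUL7H46877.2, named ribosomal protein L27e (7H, 395737279 to 395737452). HVUL4H57185.2, a tRNA modification GTPase (4H, 192762901 to 192781241), and HVUL7H60004.2, a 3-isopropylmalate dehydrogenase of leucine synthesis (7H, 284196727 to 284257405), completed this set. Each had an adjusted p of 0.00165 in Fisher's exact test (n = 10 per line). With the stricter threshold HVUL5H14858.2, HVUL5H45972.2, HVUL2H31716.2 and HVUL6H10324.2 were not called, nor were they with equal numbers of strongest peaks. Their differences in the share of libraries, G7 minus Z13, were then -0.5, -0.5, -0.2 and -0.6 with the stricter threshold. With equal numbers these were -0.4, -0.2, -0.1 and -0.7, so little of the contrast was left at HVUL2H31716.2. HVUL2H06661.2, HVUL1H52022.2 and HVUL7H60004.2 were not called with intergenic peaks assigned, at differences of -0.4, -0.8 and -0.8.

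The reverse, 10 of 10 G7 and 0 of 10 Z13 libraries at the same adjusted p of 0.00165 in Fisher's exact test, held for HVUL2H59935.2, a calmodulin-dependent protein kinase (2H, 118126649 to 118128749). It also held for HVUL4H52731.2, named for the catalytic subunit of AMP-activated kinase (4H, 204817926 to 204845430), and HVUL5H57500.2, an L-ascorbate oxidase (5H, 221230287 to 221230694). The other genes named by the rule in this direction had no KEGG name: HVUL2H50730.2, HVUL4H22299.2, HVUL1H48702.2, HVUL4H42453.2, HVUL7H21511.2, HVUL5H55897.2 and HVUL3H32512.2. Of the 20 genes named in both directions, 8 of 20 kept their call with the stricter threshold and 15 of 20 with equal numbers of peaks, and of the 18 tested, 10 kept it with intergenic peaks assigned and 17 by overlap with the gene body. With the stricter threshold each of the 10 genes of G7 except HVUL1H48702.2 and HVUL4H42453.2 lost its call, and HVUL5H57500.2 also with equal numbers. Under that threshold the G7 genes that lost it still differed by 0.6 to 0.8 in the share of libraries. With intergenic peaks HVUL2H59935.2, HVUL4H52731.2, HVUL4H22299.2, HVUL4H42453.2 and HVUL3H32512.2 lost their calls, at differences of 0.1 to 0.8. By overlap HVUL4H22299.2 also lost its call, at a difference of 0.1.

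**Figure D3:**
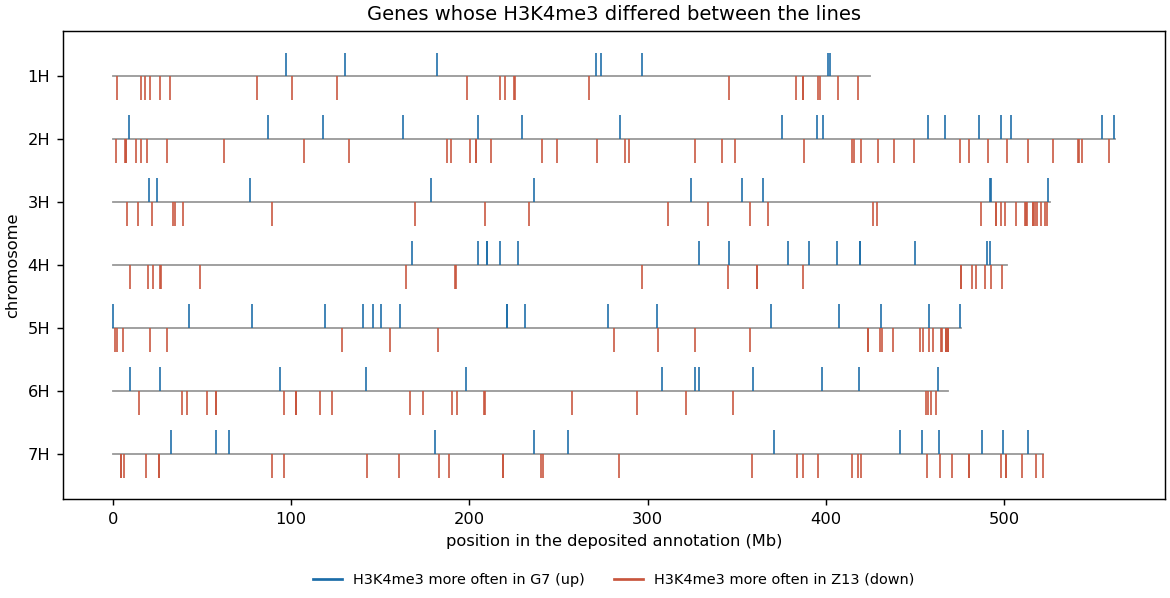
Positions (Mb) on the 7 chromosomes of the 304 called genes that have a position. Blue ticks upward are genes with H3K4me3 more often in G7, red ticks downward more often in Z13. Calls in both directions are found on each chromosome.

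Among the lists, 8 of 256 tested NLR genes were called, 2 in G7 and 6 in Z13, and 8 adjusted over the list alone. Of the F-box and ubiquitin ligases 5 of 221 were called, and 6 adjusted over the list alone. Of the added receptor kinases 7 of 443 were called, and 7 adjusted over the list alone. No WRKY, pathogenesis-related, redox or MLO gene was called. No list was enriched among the called genes (Fisher's exact test, smallest adjusted p = 0.853). With peaks under the stricter threshold 80 genes were called, 15 in G7 and 65 in Z13. Intergenic peaks assigned gave 166 (47 and 119), strata by time point 121 (24 and 97) and equal numbers of peaks 278 (83 and 195). Without the G7 6 h library of replicate 2 there were 369 calls, 149 in G7 and 220 in Z13.

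For H3K27me3, Fisher's exact test called 0 of 18678 genes between lines, with 443 at an unadjusted p under 0.05 and a smallest adjusted p of 0.101. The smallest p values were those of HVUL6H01205.2, the P450 enzyme CYP79A1 (0 of 10 G7 and 10 of 10 Z13 libraries, adjusted p = 0.101 in Fisher's exact test) and HVUL2H29636.2, a ubiquitin hydrolase (10 of 10 and 0 of 10). HVUL1H25700.2, a chalcone synthase, and HVUL3H27165.2, a hydroxycinnamoyltransferase, each had a peak in 0 of 10 G7 and 9 of 10 Z13 libraries (adjusted p = 0.202, Fisher's exact test). Of the phenylpropanoid list, 2 of 159 genes passed adjusted over the list alone. HVUL4H26135.2 had a peak in 9 of 10 G7 and 0 of 10 Z13 libraries and HVUL6H47055.2 in 10 and 1. Leaving out libraries with short lists gave 85 calls, 84 of them in Z13. This left out Z13 lists of 8351, 4490, 14978 and 8682 peaks but of G7 only that of 5330. The direction of these calls therefore cannot be told apart from list length. Equal numbers of peaks gave 18 calls, and leaving out the Z13 168 h library of replicate 1 gave 7, among them HVUL6H01205.2, HVUL2H29636.2, HVUL3H27165.2 and HVUL1H25700.2.

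Between lines, 1 of 22 lists passed for each mark. The receptor-like kinase list, 11 genes named for the chitin receptor CERK1, carried H3K4me3 less often in G7, by a log2 ratio of -0.18 (adjusted exact permutation p = 0.0113). Its member HVUL3H36194.2 (3H, 22073441 to 22074607) had a peak in 0 of 10 G7 and 8 of 10 Z13 libraries (adjusted p = 0.0431, Fisher's exact test), and HVUL3H24530.2 and HVUL7H28390.2 each in 6 and 8. The 17 MLO genes carried H3K27me3 more often in G7, by a log2 ratio of 0.93 (adjusted exact permutation p = 0.0283), without any single gene called. The share of MLO genes with H3K27me3 was 22.4% ± 12.3 in G7 and 17.1% ± 17.0 in Z13 (SD, n = 10 each). HVUL1H09108.2 had a peak in 9 of 10 G7 and 5 of 10 Z13 libraries, HVUL7H40652.2 in 6 and 2 and HVUL6H05820.2 in 3 and 0. HVUL2H03411.2 and HVUL4H38555.2 (0 and 2 each) and HVUL5H28831.2 (1 and 3) went the other way. All 17 genes share the name mlo protein, which does not tell which of them bear on powdery mildew susceptibility. The CERK1 call ended under each other gene assignment and peak selection tried (adjusted exact permutation p = 0.102 to 0.820). It also ended without the G7 72 h library of either replicate (adjusted exact permutation p = 0.0622). Its log2 ratio in these cases ran from -0.13 to -0.26. The MLO call ended under each of these assignments and selections except overlap with the gene body (adjusted exact permutation p = 0.0226). Its log2 ratio was 0.35 with intergenic peaks, 0.64 within 2000 bp, 0.15 with the stricter threshold and 0.88 with equal numbers. The call also ended without either library of G7 at 0, 36 or 168 h or of Z13 at 0 or 72 h. The log2 ratio was then 0.80 to 0.98 (adjusted exact permutation p = 0.0509 to 0.0905). NLR genes did not pass between lines for H3K4me3 (log2 ratio -0.05, adjusted exact permutation p = 0.920) or H3K27me3 (-0.02, adjusted exact permutation p = 0.851).

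Of the preset loci, the names matched MLO, NPR1, the salicylate receptor, and SGT1. All 5 NPR1 genes carried H3K4me3 in 10 of 10 libraries of each line, and 14 of 17 MLO genes in 10 or more of the 20 libraries. The SGT1 pattern matched 19 genes, of which HVUL3H51290.2 (3H, 286492511 to 286499056) is named for the co-chaperone SGT1 and the others for a salicylic acid glucosyltransferase of the same symbol. HVUL3H51290.2 carried H3K4me3 in 20 of 20 libraries and H3K27me3 in 0 of 20. No gene of these loci was called.

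The next comparison asked what changed after the fungus was applied. No library after 0 h is labelled as unsprayed or mock-sprayed. Infection therefore cannot be told apart from the spraying itself, leaf age or time of sampling. For 0 h against infected leaves the exact conditional test called 0 genes for H3K4me3 (59 at an unadjusted p under 0.05) and 0 for H3K27me3 (85). Among the smallest p values were H3K4me3 at HVUL7H08038.2, autophagy protein ATG12 (0 of 4 libraries at 0 h, 12 of 16 after), at HVUL6H47466.2 and HVUL6H42419.2 (0 of 4 and 13 of 16 each), and at HVUL1H05252.2, named BAK1, and HVUL4H51638.2 (3 of 4 and 1 of 16 each). H3K27me3 was found at HVUL2H01296.2 in 0 of 4 and 14 of 16 libraries, at HVUL4H37773.2 in 0 and 13, and at HVUL2H24240.2 in 0 and 12, and at HVUL1H14005.2, HVUL5H36335.2 and HVUL1H23733.2 in 3 of 4 and 0 of 16 each. No list passed. The smallest adjusted exact permutation p was 0.922 for H3K4me3 and 0.0815 for H3K27me3, shared by MADS and homeobox factors (log2 ratio after infection 0.73) and calcium signalling (-0.40). The G7 0 h library of replicate 1, with a peak in 790 genes, is 1 of the 4 libraries at 0 h, and without it these values were 0.30 and -0.38 (adjusted exact permutation p = 0.435 each). With equal numbers of peaks 2 other lists passed for H3K27me3, but not MADS and homeobox factors or calcium signalling. NLR genes had log2 ratios of -0.07 for H3K4me3 (adjusted exact permutation p = 0.922) and 0.19 for H3K27me3 (adjusted exact permutation p = 0.573). The change from 0 h to infected leaves differed between lines for no list (smallest adjusted exact permutation p = 0.95 for H3K4me3 and 0.125 for H3K27me3).

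Between early and late leaves the exact conditional test called 0 genes for H3K4me3 (51 at an unadjusted p under 0.05) and 0 for H3K27me3 (716, of which 704 had a peak more often late). The smallest H3K27me3 p values included HVUL3H20483.2, a MADS-box factor (0 of 8 early and 10 of 12 late libraries), HVUL5H36374.2, a MYB protein (1 and 11), HVUL7H25879.2, a carboxypeptidase (2 and 12), HVUL6H13467.2, a histone H3 gene (5 and 0), and HVUL2H24735.2 and HVUL7H04131.2 (8 and 4 each). For H3K4me3 they included the F-box gene HVUL6H04888.2 and HVUL1H35409.2 (3 of 8 and 12 of 12 each), HVUL1H44912.2 (0 and 6) and, more often early, HVUL1H23733.2 (4 and 0). No gene had an adjusted p under 0.819 in the exact conditional test for H3K27me3, and it was 1 for H3K4me3.

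Single times were compared with 0 h within a line by genes with a peak in both replicates of one time and neither of the other. This gave 120 to 780 genes per comparison for H3K4me3 and 265 to 2467 for H3K27me3. In 1 of 8 comparisons of each mark the count was above both other ways of splitting the same 4 libraries, where chance alone would give about 1 of 3: H3K4me3 in Z13 at 36 h (780 genes against 364) and H3K27me3 in G7 at 36 h (2467 against 695). With 2 libraries against 2 an exact test of the presence of a peak cannot pass 0.05. The G7 0 h library of H3K27me3 that enters the latter had 790 genes, the fewest of its mark.

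The mean similarity of replicates of one time point was not above that of replicates of different time points for H3K4me3 (Jaccard index 0.417 ± 0.108, n = 10 pairs, against 0.438 ± 0.131, n = 40; exact permutation p = 0.945). For H3K27me3 the values were 0.187 ± 0.160 and 0.159 ± 0.123 (one-sided exact permutation p = 0.0747), and p was 0.0490 without the Z13 36 h library of either replicate. Over all pairs, mean similarity within a line exceeded that between lines by 0.0226 for H3K4me3 (one-sided exact permutation p = 0.0324) and 0.0312 for H3K27me3 (one-sided exact permutation p = 0.0252), in a test added after the data were examined. Over pairs of libraries with different replicate numbers alone, the differences were -0.00226 and 0.0103 and did not pass (one-sided exact permutation p = 0.635 and 0.217). Over pairs with the same replicate number they were 0.0508 and 0.0601 (one-sided exact permutation p = 0.0147 and 0.0293). The excess thus depends on which pairs are counted and was larger where replicate numbers were shared. G7 lists held 35337 ± 10697 H3K4me3 peaks and Z13 lists 33658 ± 4807 (SD, n = 10 each), and 33012 ± 21370 and 28479 ± 20732 H3K27me3 peaks. At 0 h lists held 37325 ± 9457 H3K4me3 peaks (SD, n = 4) and after infection 33790 ± 7932 (SD, n = 16), and H3K27me3 peaks covered 33.5 ± 31.0 and 47.9 ± 40.0 Mb. None of the 8 comparisons of peak number or covered length passed (smallest exact permutation p = 0.482).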

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

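Each of 32 sets of 10 libraries of a line and mark was searched for a library far from the others, and 3 were found. Chance marks about 1 in 20 sets. The G7 6 h H3K4me3 library of replicate 2 had a mean correlation over genes of 0.496 with the other H3K4me3 libraries, the lowest of its line, and the fewest peaks of its mark (17616). The Z13 72 h H3K4me3 library of replicate 1 had a mean correlation of 0.637, the lowest of its line. The Z13 168 h H3K27me3 library of replicate 2 had 47.9% of its peaks in the outer 10% at either end of a chromosome, the lowest share among Z13 libraries of the mark, and the most peaks (70975).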

How the results depend on the processing

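Alternatives added after the data were examined are assignment by overlap with the gene body, those for lists against other genes, for peak number after infection and for gained and lost genes, 3 filters of the time comparisons, and the block and left-out libraries for gene lists. The association of both marks kept its side of the threshold under every alternative tried, but equal numbers of peaks were not among these. The time comparisons gave 0 genes under each, but for 0 h against infected leaves simulated changes were mostly not recovered, so a count of 0 there shows no stability. For the changes below the cause was not tested.

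H3K4me3 calls between lines (305) were 166 with intergenic peaks assigned, 80 with the stricter threshold and 121 stratified by time point. They were 307 to 369 with a library left out. The 121 stratified calls, 24 in G7 and 97 in Z13, match in number the genes with a peak in 10 of 10 and 0 of 10 libraries. Only such genes reach the smallest p of the stratified test. H3K27me3 calls between lines (0) were 18 with equal numbers of peaks, 85 without short lists, 7 by overlap with the gene body and 0 to 7 with a library left out, 7 being without the Z13 168 h library of replicate 1. The replicate numbers were not taken to pair the samples, since only 13 of 45 correlations of deviations between groups were over 0.1 for H3K4me3 and 19 of 45 for H3K27me3, and they ran from -0.37 to 0.45 for H3K4me3 and from -0.44 to 0.45 for H3K27me3. With the replicate block H3K4me3 gave 279 calls, all among the 305, and H3K27me3 0 between lines, and 0 lists passed between lines for either mark (receptor-like kinases, adjusted exact permutation p = 0.0859, and MLO genes, 0.129).

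The 1 list that passed between lines became 0 for H3K4me3 with intergenic peaks assigned, within 2000 bp of the start, with equal numbers of peaks and by overlap with the gene body, and 0 to 1 with a library left out, 0 without either G7 72 h library. With the stricter threshold 1 H3K4me3 list passed, but not that of the receptor-like kinases (adjusted exact permutation p = 0.495). For H3K27me3 it became 0 with intergenic peaks, within 2000 bp, with the stricter threshold and with equal numbers of peaks, and 0 to 1 with a library left out, 0 without either library of G7 at 0, 36 or 168 h or of Z13 at 0 or 72 h. Between 0 h and infected leaves 2 H3K27me3 lists passed with equal numbers of peaks, neither of them MADS and homeobox factors or calcium signalling, and 4 of 8 comparisons of gained and lost genes then exceeded the other splits, where chance alone would give about 1 of 3. H3K27me3 lists against other genes numbered 11 with the stricter threshold.

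With equal numbers of peaks, H3K4me3 log2 ratios to other genes turned to -0.31 for pathogenesis-related, -0.47 for redox, -0.48 for callose and cell wall, 0.22 for ribosomal, -0.51 for MADS and homeobox, -0.24 for histone and -0.24 for added receptor kinase genes. With the stricter threshold these were -0.41, -0.40, -0.35, 0.12, -0.36, -0.13 and -0.27. MADS and homeobox genes gave -0.037 with intergenic peaks, and jasmonate and ethylene genes 0.042 within 2000 bp and 0.028 by overlap. For H3K27me3, equal numbers gave -0.063 for jasmonate and ethylene, 0.77 for transposon and -0.14 for added receptor kinase genes. The stricter threshold gave 0.28 for calcium, 0.43 for SNARE, 0.74 for photosynthesis, 0.24 for chromatin modifier, 0.16 for histone, 2.1 for transposon and -0.25 for added receptor kinase genes. Values above 0 under this threshold may be raised by the 0.5 added to each count. MLO genes gave -0.12 with intergenic peaks and -0.066 within 2000 bp.

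The H3K27me3 log2 ratio of NLR genes between lines was 0.0064 within 2000 bp, 0.52 with the stricter threshold, 0.21 with equal numbers, 0.050 by overlap and -0.067 to 0.028 with a library left out. After infection it was -0.13 with equal numbers. For H3K4me3 it ran from -0.088 to 0.00013 between lines and from -0.12 to 0.0045 after infection with a library left out.

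Uncalled genes also turned, in the share of libraries. HVUL7H47941.2 gave -0.19, HVUL2H24735.2 -0.12 and HVUL7H04131.2 -0.17 with the stricter threshold. HVUL4H38115.2 gave -0.042 within 2000 bp and by overlap, and HVUL6H13467.2 and HVUL7H04131.2 -0.042 by overlap.

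Log2 ratios of G7 to Z13 with the stricter threshold were -0.18 for H3K4me3 peak number, -0.19 for H3K4me3 covered length and -0.23 for H3K27me3 covered length. With a library left out they ran from -0.047 to 0.12, from -0.072 to 0.19 and from -0.32 to 0.33. For 0 h over infected leaves they ran from -0.0069 to 0.26 (H3K4me3 peak number), -0.12 to 0.31 (H3K4me3 covered length), -0.50 to 0.51 (H3K27me3 peak number) and -1.06 to 0.15 (H3K27me3 covered length). The excess similarity of H3K27me3 replicates of one time was 0.0193 by peaks overlapped by 1 bp (exact permutation p = 0.0261) and 0.0107 to 0.0403 with a library left out, passing without the Z13 36 h library of either replicate (0.0302, exact permutation p = 0.0490).

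List length differed up to 15.8 times between replicates of H3K27me3, which limits what presence of a peak can show.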

Other observations

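The test of peaks placed without regard to genes was chosen after its result was seen, as was that of list length per direction, and those of neighbouring genes and of H3K27me3 at called genes were added after the data were examined.

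Among the 305 genes called between lines, some names occurred more than once, which was seen only after the calls were made and was not tested. RPM1 was the name of 6 genes with H3K4me3 more often in Z13 and 2 more often in G7. Argonaute AGO1, a core protein of small RNA silencing, EFR, the splicing protein LSm2 and 3-isopropylmalate dehydrogenase each named 2 genes more often in Z13. Phosphoethanolamine N-methyltransferase, an enzyme of choline synthesis, named 2 genes more often in G7. Single genes more often in Z13 included a salicylate hydroxylase, an enzyme that breaks down salicylate, and a MAP kinase kinase of the type 4 and 5. Neither KEGG name nor GO term was deposited for 165 of the 305 genes. At HVUL6H10324.2, the STUB1 gene with H3K4me3 in Z13, H3K27me3 was found in 8 of 10 Z13 and 0 of 10 G7 libraries. At HVUL2H50730.2, with H3K4me3 in G7, H3K27me3 was found in 6 of 10 Z13 and 0 of 10 G7 libraries.

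The longer H3K4me3 list of each G7 time was that of replicate 1, in 5 of 5 times, by 1.32 to 2.28 times. Replicate 1 had the longer list at 3 of 5 times for H3K4me3 in Z13. For H3K27me3 it did so at 2 of 5 times in G7 and 1 of 5 in Z13.

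H3K4me3 differed between lines at 305 genes. Of 100 splits of the 20 libraries 1, the real one, called as many, and the highest other called 0. Random grouping of these libraries thus does not account for the count, as far as 100 splits can show. The splits do not bear on differences in how the libraries of each line were handled. For peak lists of different length, the planned test asked how many of the 305 genes were called again with equal numbers of peaks. Of the 278 genes then called, 135 were among the 305, which met neither outcome set beforehand. The later test per direction argues against length as the whole cause. It called 83 genes in G7 and 195 in Z13 (95 and 210 as reported), and the highest of the other splits called 0. In addition, 24 genes had a peak in each G7 list, from 17616 peaks up, but in no Z13 list, of 23570 peaks or more. For single genes length stays open, since 135 of the 305 were called again and the other 170 fell from 9.09 ± 0.827 to 3.51 ± 2.48 of 10 libraries of the line with the mark (SD, n = 170 genes), as only the strongest peaks were kept. A candidate explanation is sequence that is missing or does not map in the line without the mark, where H3K27me3 was found in 8.56% of libraries against 19.7% in the other, a difference of -11.2 percentage points (exact permutation p = 0.000514), but both marks also occurred together over all genes (1.10 times as often as independent marks would), and while 128 genes had H3K27me3 more often in the line with H3K4me3, 37 had it more often in the line without and 131 had none in any library. Segments that differ between the lines may contribute, since neighbouring genes were called in the same direction 6.30 times as often as at random (permutation p = 0.0001, the smallest these permutations can give). But only 34 genes lay in such pairs. A single peak can also be assigned to several genes, and how many of these pairs share a peak was not examined, so this excess does not show segments. A regulatory difference stays open, as untested.

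The G7 0 h H3K27me3 library of replicate 1 stood apart from the others of its mark, with a mean correlation over genes of 0.123 with them. Its mean correlation with H3K4me3 libraries was 0.0172, and the lowest among those libraries was 0.402. This does not test for a wrong mark label. With a peak in 790 genes, against 11138 to 23564 in H3K4me3 libraries, a high correlation was out of reach. In H3K4me3 libraries 44.9% to 67.9% of peaks lay in a gene or promoter. Peaks placed without regard to genes may contribute, since 5.27% of its peaks lay in a gene or promoter, which take up 6.41% of the chromosomes, against 13.7% to 35.0% in the other libraries of the mark, but 40.3% of its peaks were overlapped by its replicate and a median of 15.3% by another library of the mark. No biological explanation was tested. Without this library H3K27me3 called 0 genes between lines, as with it.

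More genes carried H3K27me3 late than early at an unadjusted p under 0.05. With equal numbers of peaks 84.5% of 58 such genes were found more often late (Wilson 95% interval 73.1% to 91.6%), which does not settle whether list length could be the cause. No gene was called, so 100 of 100 splits called as many by construction, but the highest other split called 927. What that split separates, and how far it overlaps with early and late, was not examined.

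The remaining per-gene tests called 0 genes, which every split reaches (100 of 100), so the splits do not bear on chance for them; the highest other split gave 0 in each.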
